A study of Schmidtea mediterranea with 89 samples.

How the data were processed

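RNA was measured in 89 libraries of planarian stem cells (neoblasts, the dividing adult stem cells of the flatworm Schmidtea mediterranea) that had been sorted with a fluorescent dye for nuclear DNA and are called SiRNeoblasts in the labels. Per the labels' protocols, cells were kept at 22 degrees in a serum-containing medium, lysed, and their RNA was copied by template switching, amplified by PCR and cut with Tn5 transposase. No molecular identifiers are mentioned in the labels, so counts are of amplified fragments, and intervals or floors made from them cover counting error only. The libraries form 5 experiments and 30 groups of 3 libraries, except for the polyacrylamide gel at 3 days, which has 2. Nothing in the labels says whether libraries of a group came from separate cultures or animals, so every p-value measures only the spread between these libraries, which may be technical.

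The authors deposited 1 table per experiment. Per the labels, experiments 1, 2 and 3 hold estimated counts, seen in the values as numbers that are not whole, and experiments 4 and 5 hold whole counts, also deposited without normalization. Kallisto 0.46.2 and R 4.0.5 are named in the submitters' processing notes with no role or order, and the transcriptome, annotation, genome build and filters are not given in the sources used here. Between 65.8% and 74.1% of the non-zero deposited counts of experiments 1 to 3 were fractional and none were in experiments 4 and 5. How the whole counts were made is not given in the sources used here, and no model was fitted across tables. Shares, ranges and the choice of the most abundant and the silent identifiers do draw on several tables, which were made separately. Every table lists 36035 identifiers that start with SMED3 and no gene names, coordinates or products. No reference annotation was used here. The 17 gene lists that had been fixed, on replication, mitosis, neoblasts, differentiated cell types, stress and metabolism, matched 0 members, so no list test could be run. Identifiers are therefore printed as deposited, with no gene behind them, and at most 2 that were higher and 2 that were lower are named per comparison.

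Estimated counts were rounded to whole numbers. Within each experiment, identifiers were kept by the default expression filter of edgeR 4.0.16 on the groups, libraries were scaled with TMM (trimmed mean of M values), and all groups were fitted together with 1 mean per group, so that groups of 3 shared 1 estimate of the spread. The quasi-likelihood F test of edgeR, two-sided, gave log2 fold changes, and the Benjamini-Hochberg adjusted p threshold was 0.05 in R 4.3.3. Standard errors (SE) were derived from it, as the absolute log2 fold change divided by the square root of F. Comparisons, gene lists, test, samples and covariates, the rule for named identifiers and the alternatives were fixed before the data were examined. The named identifiers were the highest and lowest log2 fold changes among calls with a mean of at least 10 CPM (the usual depth-scaled counts, made with edgeR from effective library sizes) over both groups and no overlap between the libraries of the groups. Of these, mainly those whose call held when each library was left out in turn are printed, a choice made after their values were seen. SMED30032887, and identifiers carried from 1 comparison into another where this rule did not name them (SMED30008091, SMED30022580, SMED30023111 and SMED30024144), were also chosen after their values were seen. Adjusted p-values in the text are from this edgeR test unless another tool is named. Counts of 5 calls or fewer by this test are given with their identifiers, which were then chosen after their values were seen.

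Further measures per library were chosen after seeing the data. The share of counts in the 4 identifiers with the highest mean share over all libraries was taken from the total count. The number of detected identifiers counts those above 0. For the culture-response score, the identifiers called lower (the fell group) and higher (the rose group) after 3 days of flat culture in every one of the other experiments with uncultured cells were used, and the score is the mean log2 CPM (prior count 2) of the rose group minus that of the fell group. The silent share is the percent of counts, outside the 4 most abundant identifiers, in identifiers below 0.5 CPM in every uncultured library of the other experiments. Single comparisons of these measures used exact permutation tests, two-sided, whose smallest possible p with 3 libraries against 3 is 0.1. Over several days and experiments, libraries were permuted within each of them in an exact stratified permutation test, two-sided, with Benjamini-Hochberg adjustment over 20 tests. The fell and rose groups were also tested against all other identifiers with camera in limma 3.58.1, with the preset correlation of 0.01 between identifiers and with an estimated one, adjusted over all comparisons.

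Alternatives were RLE size factors (the DESeq2 method) in place of TMM, no low-count filter, the replicate number as a block, a fit of only the 2 groups compared, the DESeq2 1.42.0 Wald test, and leaving out each library in turn. Added after seeing the data were removal of the 4 most abundant identifiers, a fit of only identifiers of at least 10 CPM, experiment 5 without its day 7 libraries, and halved counts of 1 library. The pairwise chi-square per degree of freedom between libraries of a group was at least 6.58, so no library repeats another within sampling noise.

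The test was checked on simulated counts drawn from the real means and library sizes. Changes were planted only in identifiers with a mean of about 10 CPM or more. The recovered shares therefore do not cover the lower identifiers among those tested. In the simulation of the U-bottom comparison at 3 days in experiment 3, 82.1% of changes of 1 on the log2 scale were recovered among 20949 identifiers. The simulated aggregate comparison of experiment 1 recovered 0 of 67 changes of that size, 32.8% of changes of 2 and 95.5% of changes of 3 among 18241 identifiers. For AggreWell in experiment 2 the shares were 25.4%, 95.5% and 100.0% of changes of 1, 2 and 3 among 18266. For the mouse feeder at 3 days in experiment 4 they were 1.49%, 4.48% and 22.7% among 26107, and for the U-bottom plate at 3 days in experiment 5 they were 2.99%, 55.2% and 97.0% among 24174. In the simulated extract comparison at 7 days they were 4.48%, 49.3% and 89.4% among 24174. The highest share of false calls was 9.57%, in the simulation of experiment 1. Total counts ran from 3333661 to 42691160 per library, and 3 counts, the floor for an absent identifier, are 9e-05% of the smallest library.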

Results

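The expression of 36035 identifiers was measured in 89 libraries of planarian neoblasts, sorted by a nuclear DNA dye and either lysed uncultured or after 1 to 7 days in culture. Experiment 1 compared cells in aggregates with non-aggregating cells at 2 days. Experiment 2 compared AggreWell plates, whose microwells gather cells into clusters, with flat plates at 1 day. Experiment 3 held uncultured cells, flat plates and a soft polyacrylamide (PA) gel of 100 Pa at 1, 2 and 3 days, and U-bottom plates, whose round wells collect cells at the bottom, at 1 and 3 days. Experiment 4 held uncultured cells, flat plates, and feeder layers of HFF1 (a human foreskin fibroblast line) or MEF (mouse embryonic fibroblasts) at 1 and 3 days. Experiment 5 held uncultured cells, flat plates, U-bottom plates and U-bottom plates with planarian tissue extract at 1, 3 and 7 days. Every group had 3 libraries, except the PA gel at 3 days with 2. The total count per library ran from 17293102 to 24128450 in experiment 1, 10566779 to 17296616 in experiment 2, 12386601 to 25588459 in experiment 3, 6775383 to 42691160 in experiment 4 and 3333661 to 30686937 in experiment 5.

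A few identifiers held a large share of the counts. Over all 89 libraries SMED30032887 took 27.0% of the counts of a library on average, SMED30027385 17.9%, SMED30027845 12.5% and SMED30026765 1.74%. The shares differed between experiments, and in flat replicate 1 at 3 days of experiment 4 the most abundant identifier held 48.5% of the counts and the 4 together 50.1%. Together these 4 held between 27.0% and 58.9% of the counts in experiment 4 and between 54.6% and 84.6% in experiment 3. The number of detected identifiers ranged from 15452 in a U-bottom library of experiment 5 to 31993 in a flat library of experiment 4. That U-bottom library was the shallowest of all, with 3333661 counts, and detection was not corrected for depth.

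**Figure D1:**
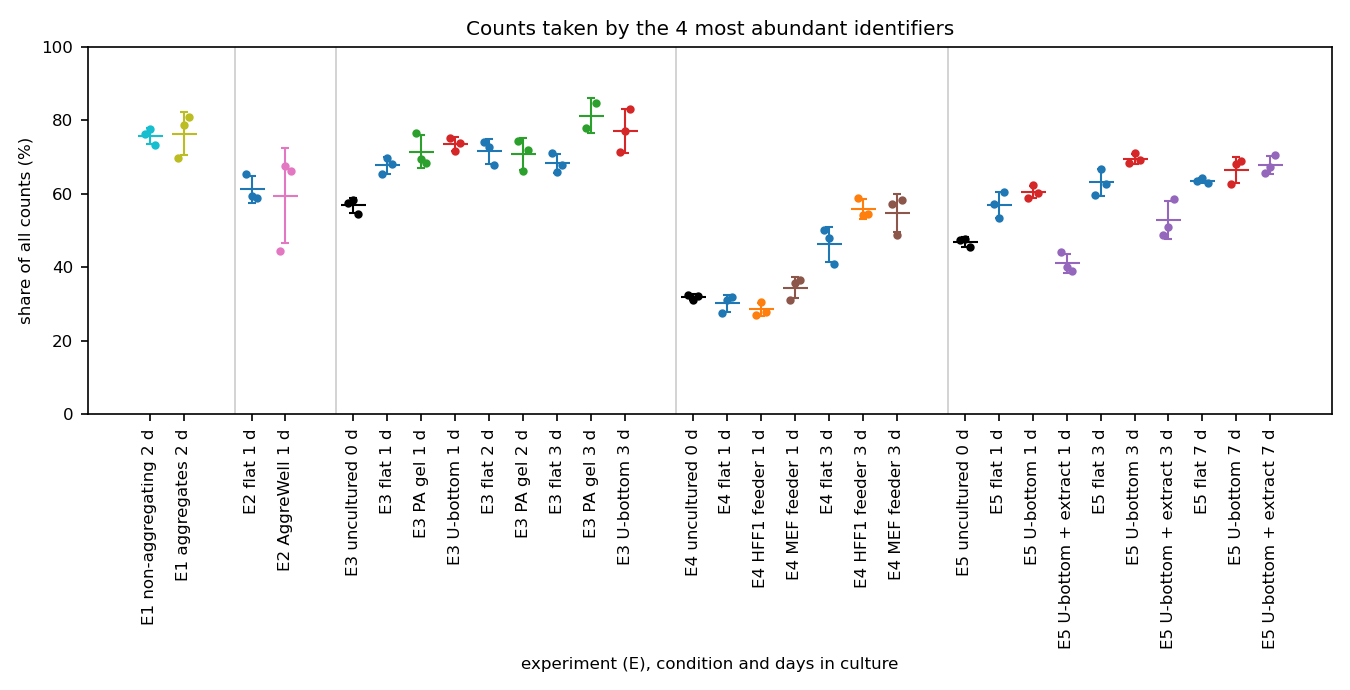
Percent of all counts held by the 4 most abundant identifiers (y axis) in each library (points), by experiment, condition and days in culture (x axis), with group means and SD as bars. The extract libraries at 1 day averaged 41.0%, against 60.5% in the U-bottom libraries without extract.

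Culture on a flat plate changed many identifiers relative to uncultured cells. SMED30023111 rose in each experiment with uncultured cells, with log2 fold changes at 3 days of 4.32 in experiment 3, 4.49 in experiment 4 and 4.81 in experiment 5. In experiment 5 it went from 4.59 ± 0.74 CPM (SD, n = 3) in uncultured cells to 129 ± 12.1 CPM (n = 3) at 3 days. SMED30022580 moved the other way, with log2 fold changes of -7.58, -6.0 and -6.42 at 3 days in experiments 3, 4 and 5. These 2 were picked out after their values were seen. Among 18512 identifiers tested in all 3 experiments, 107 fell and 119 rose at 3 days in every one, where independent lists would share 2.43 and 6.56.

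In experiment 3, 5876 of 20949 identifiers were called after 1 day on a flat plate (2691 higher and 3185 lower), 7890 after 2 days (3656 and 4234) and 8765 after 3 days (3886 and 4879). SMED30008091 rose from 1.15 ± 0.47 CPM (n = 3) to 23.4 ± 1.28 CPM (n = 3) at 1 day, a log2 fold change of 4.33 (SE 0.27, adjusted p = 1.52e-12). SMED30002860 fell from 24.1 ± 4.04 to 0.505 ± 0.169 CPM over the same day, a log2 fold change of -5.58 (SE 0.51, adjusted p = 1.93e-09). At 3 days SMED30021545 had dropped from 37.3 ± 11.4 to 0.0875 ± 0.0802 CPM. Detected identifiers went down from 28015 ± 363 in uncultured libraries to 21016 ± 1614 at 3 days (n = 3 each), without overlap, at an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow. The 1-day count was 3901 without flat replicate 3 and 9659 with only the compared groups fitted. The excess of lower calls turned without a low-count filter at 1 day (3069 higher and 2825 lower). With only identifiers of at least 10 CPM fitted it turned at 2 days (1545 and 1526) and 3 days (1584 and 1519). It did not turn in that fit at 1 day (1286 and 1417). In the fit of all identifiers, the calls at 10 CPM and above were mostly higher at each day. They were 1331 higher and 1041 lower at 1 day, 1642 and 1177 at 2 days and 1904 and 1128 at 3 days.

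In experiment 4, where feeders were tested, flat culture called 4352 of 26107 identifiers at 1 day (3532 higher and 820 lower) and 4134 at 3 days (3582 and 552). Of these calls 738 at 1 day and 656 at 3 days had a mean of at least 10 CPM over all libraries of the experiment. SMED30028163 rose from 0.248 ± 0.254 to 41.5 ± 18.7 CPM at 3 days (n = 3 each), a log2 fold change of 7.38 (SE 1.13, adjusted p = 0.000123). These counts fell when any 1 uncultured library was left out. Without uncultured replicate 1, 2 or 3 they were 1393, 662 and 1092 at 1 day and 1390, 667 and 1202 at 3 days. Without flat replicate 2 they were 1935 at 1 day and 2247 at 3 days, and with only the compared groups fitted the calls were 927 higher and 747 lower at 1 day and 1765 and 1126 at 3 days.

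In experiment 5 flat culture called 166 of 24174 identifiers at 1 day (98 higher and 68 lower), 892 at 3 days (539 and 353) and 2466 at 7 days (1550 and 916). SMED30023699 rose from 0.928 ± 0.172 to 25.8 ± 2.41 CPM at 1 day (n = 3 each), a log2 fold change of 4.78 (SE 0.72, adjusted p = 0.000153). At 7 days SMED30027627 had risen from 0.233 ± 0.251 to 73.9 ± 27.8 CPM, a change of 8.43 (SE 0.69, adjusted p = 8.65e-11). SMED30033690 fell at 3 days from 64.5 ± 15.5 to 0.612 ± 0.668 CPM, a change of -6.75 (SE 0.92, adjusted p = 9.73e-06). At 7 days SMED30000967 had 0 counts against 25.2 ± 4.52 CPM in uncultured cells, at least 425-fold lower against a floor of 3 counts over the group. The split into higher and lower calls depended on the fit. At 1 day it was 64 and 101 with RLE scaling, 215 and 421 by DESeq2 and 666 and 1194 with only the compared groups fitted. At 3 days it was 915 and 1247 by DESeq2, 713 and 1622 with only the compared groups and 743 and 822 without the day 7 libraries, and at 7 days 2364 and 2490 with only the compared groups. The 1-day count was 476 without the day 7 libraries and 462 without a low-count filter. It fell to 74, 74 and 81 without flat replicate 1, 2 or 3 and to 61 without uncultured replicate 2 or 3, and without these uncultured replicates it was 503 and 465 at 3 days and 1535 and 1451 at 7 days.

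The flat-culture changes of the 3 experiments, which share no libraries, correlated across identifiers, which are not independent replicates. At 3 days Pearson's r was 0.505 between experiments 3 and 5 (Spearman's rho 0.531, 19362 identifiers), 0.397 between 3 and 4 (rho 0.428, 19249 identifiers) and 0.317 between 4 and 5 (rho 0.353, 22069 identifiers). Over identifiers of at least 10 CPM these r were 0.755, 0.513 and 0.731. At 1 day r was 0.504 between experiments 3 and 5, 0.418 between 3 and 4 and 0.189 between 4 and 5, and 0.825, 0.419 and 0.479 over identifiers of at least 10 CPM. Experiments 3 and 5 shared 297 identifiers that fell and 292 that rose at 3 days, where independent lists would share 85.5 and 98.0, and 5 were called in opposite directions. Between experiments 4 and 5, 112 fell in both and 300 rose in both, against 8.43 and 54.9. Between experiments 3 and 4, 395 fell in both and 303 rose in both, against 128 and 270.3, and 57 were called in opposite directions.

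**Figure D2:**
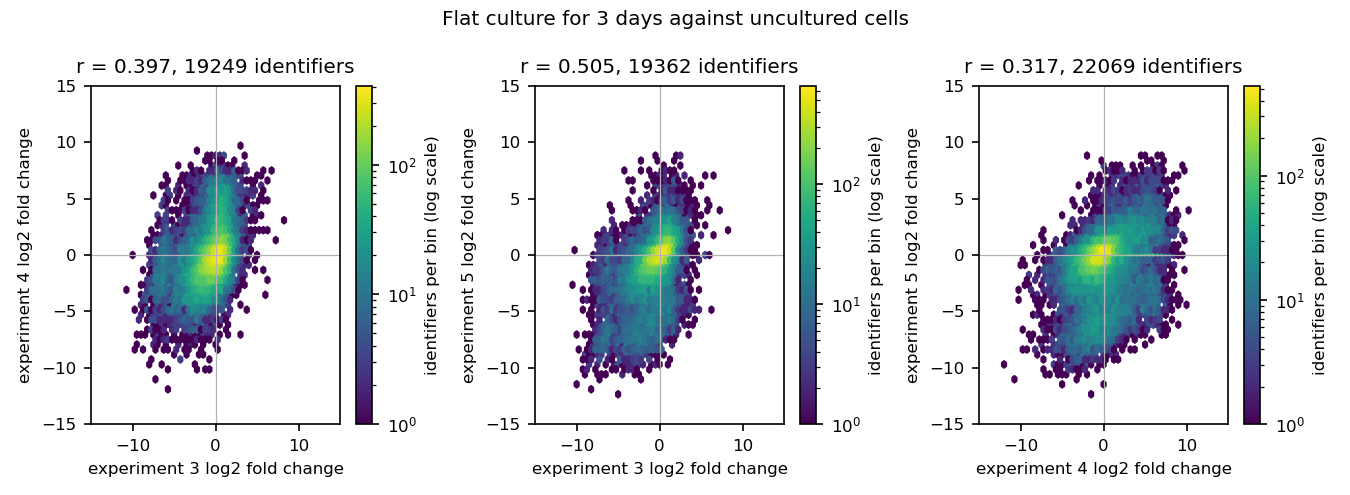
Log2 fold change of flat culture for 3 days against uncultured cells, compared between each pair of experiments (both axes), with colour giving the number of identifiers per bin on a log scale. Pearson's r was 0.397 for experiments 3 and 4, 0.505 for 3 and 5 and 0.317 for 4 and 5.

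The culture-response groups, taken from the experiments other than the one tested, moved further with time in culture in experiment 5, while the medians of the rose groups of experiments 3 and 4 changed little between days. In experiment 5 the 389 identifiers of the fell group had a median log2 fold change of -1.92 at 1 day, -2.80 at 3 days and -3.28 at 7 days, and 33, 107 and 158 of them passed the test (89, 216 and 233 adjusted over the list alone). The 277 identifiers of the rose group had medians of 0.86, 1.80 and 3.92, with 29, 119 and 182 higher (81, 165 and 221 adjusted over the list alone). With an estimated correlation between identifiers the adjusted camera p at 7 days was 4.47e-12 for the fell group and 8.38e-05 for the rose group. In experiment 3, 107 of 112 fell-group identifiers were lower at 3 days (median -2.53, adjusted p = 0.00048 with an estimated correlation) and of 282 rose-group identifiers 119, 131 and 119 were higher at 1, 2 and 3 days (127, 136 and 125 adjusted over the list alone; medians 0.91, 0.98 and 0.81, adjusted p = 0.117, 0.13 and 0.17 with an estimated correlation). In experiment 4 the 297 identifiers of the fell group had medians of -1.83 and -2.37 at 1 and 3 days, with 68 and 107 lower (85 and 131 adjusted over the list alone, adjusted p = 0.00022 and 2.02e-05 with an estimated correlation). The 292 identifiers of its rose group had medians of 1.51 and 1.57, with 122 and 119 higher (135 and 141 adjusted over the list alone, adjusted p = 3.18e-06 at both days with an estimated correlation). The response score of experiment 5 went from -2.59 ± 0.42 in uncultured cells to 0.47 ± 0.16, 2.06 ± 0.25 and 4.06 ± 0.17 at 1, 3 and 7 days on flat plates (n = 3 each).

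**Figure D3:**
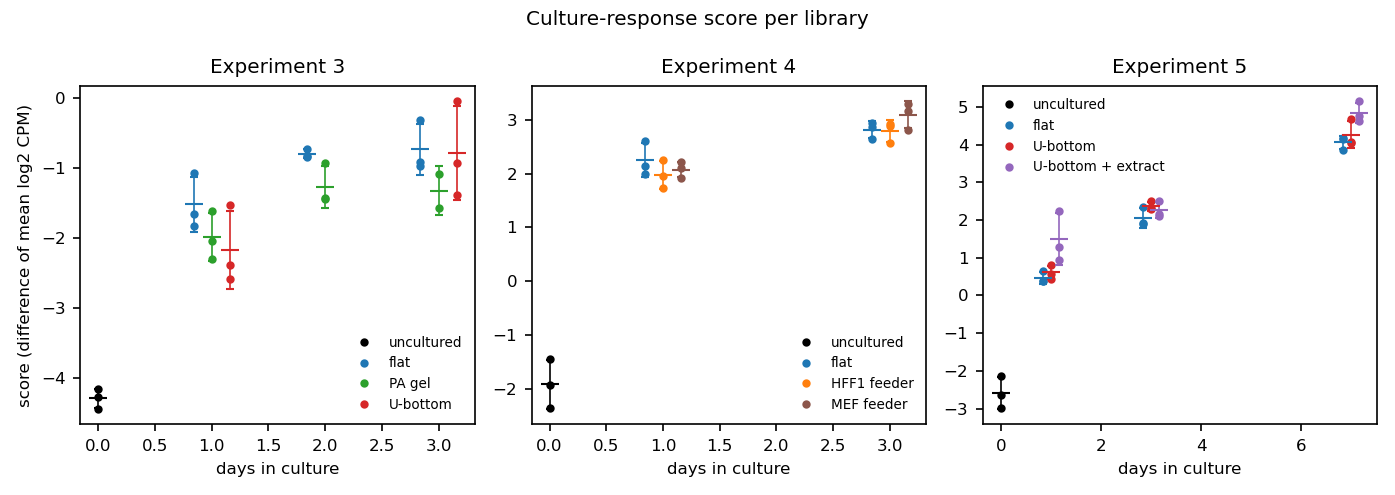
Culture-response score, the mean log2 CPM of the rose group minus that of the fell group (y axis), in each library (points) against days in culture (x axis), with group means and SD as bars; points of a day are set side by side. In experiment 5 flat libraries averaged 4.06 at 7 days and uncultured libraries -2.59.

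Experiment 1 asked how cells that had formed aggregates differ from those that had not after 2 days. No identifier of 18241 was called higher or lower in aggregates by edgeR, with 305 at an unadjusted p under 0.05, and DESeq2 called 2. Both groups had a similar share of counts in the 4 most abundant identifiers, 76.4% ± 5.87 in aggregates and 75.8% ± 2.2 in non-aggregating cells (n = 3 each, exact permutation p = 0.9). The tests given here for experiment 1 are unpaired, and a pairing of its libraries by replicate number stays open. The fell group of culture-response identifiers lay higher in aggregates, with a median of 0.47 over 98 identifiers, of which 0 passed the test (1 adjusted over the list alone), and an adjusted p of 0.473 with an estimated correlation. Without aggregate replicate 3, 1 identifier was called. The response score was 2.57 ± 1.16 in aggregates and 2.93 ± 0.51 in non-aggregating cells (exact permutation p = 0.8), and the standard errors of single identifiers of at least 10 CPM had a median of 0.54 on the log2 scale.

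Experiment 2 asked whether gathering cells in AggreWell plates changes them within 1 day. It did so widely: 3828 of 18266 identifiers were called, 2156 higher and 1672 lower than on flat plates. SMED30002216 rose from 4.36 ± 1.10 to 23.8 ± 8.12 CPM (n = 3 each), a log2 fold change of 2.45 (SE 0.36, adjusted p = 0.00268), and SMED30017965 fell from 21.5 ± 6.17 to 3.38 ± 1.18 CPM, a change of -2.66 (SE 0.38, adjusted p = 0.00268). SMED30023111, which flat culture raised in the other experiments, had a log2 fold change of -1.58 in AggreWell plates (adjusted p = 0.0113). Of 119 rose-group identifiers, 74 were higher and 19 lower (median 1.12), and of 100 fell-group identifiers, 14 were lower and 3 higher (median -0.46). Adjusted p was 0.369 and 0.256 for these groups with an estimated correlation.

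The response score of the AggreWell libraries was 2.85 ± 0.32 against 1.89 ± 0.18 on flat plates (n = 3 each), without overlap, at an exact permutation p of 0.1, the smallest possible. Counts in identifiers silent in the uncultured cells of other experiments rose with it, from 1.08% ± 0.23 to 2.32% ± 0.27, also without overlap. The count of calls was 970 without flat replicate 1, 1105 without AggreWell replicate 2 and 2384 without flat replicate 2. AggreWell replicate 1 held 44.5% of its counts in the 4 most abundant identifiers, against 67.5% and 66.3% in replicates 2 and 3, and a fit of only identifiers of at least 10 CPM called 1345 higher and 424 lower. In the fit of all identifiers, the calls at 10 CPM and above were 1076 higher and 1200 lower. Without a low-count filter the calls were 2008 higher and 2267 lower.

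U-bottom plates bring cells together without microwells, and experiment 3 compared them with flat plates at 1 and 3 days. At 1 day 2 of 20949 identifiers were called. SMED30027170 was lower, at 11.2 ± 0.87 CPM in U-bottom against 26.1 ± 3.28 CPM on flat plates and 5.44 ± 0.62 CPM in uncultured cells (n = 3 each), a log2 fold change of -1.23 (SE 0.19, adjusted p = 0.00431). SMED30023355 was higher, at 3.16 ± 2.27 CPM in U-bottom and 5.15 ± 2.40 CPM in uncultured cells against 0 counts on flat plates, with a floor of 0.0365 CPM for 3 counts over the group. No call was left without flat replicate 1, 1 without flat replicate 2 or 3, and 27 without U-bottom replicate 3, and DESeq2 called 150, none of them shared with edgeR.

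At 3 days 227 identifiers were called, 119 higher and 108 lower in U-bottom plates. SMED30024144 was higher, 80.8 ± 8.58 against 15.6 ± 4.88 CPM (n = 3 each), a log2 fold change of 2.37 (SE 0.26, adjusted p = 3.72e-06), and so was SMED30026924, 28.7 ± 7.69 against 6.47 ± 1.38 CPM (2.15, SE 0.33, adjusted p = 0.00114). SMED30023111 was lower, with a log2 fold change of -1.03 (adjusted p = 0.0375). The culture-response groups had medians of 0.11 (fell) and 0.08 (rose), at adjusted p of 0.747 and 0.978 with an estimated correlation. Of the first 2 members were higher (11 higher and 4 lower adjusted over the list alone), and of the second 2 were higher and 4 lower (2 and 6). At 1 day the medians were 0.23 and -0.46, at adjusted p of 0.165 and 0.256 with an estimated correlation, and 0 members of either group were called (3 of the fell group and 1 of the rose group higher adjusted over the list alone). The count was 136, 100 and 478 without flat replicates 1, 2 and 3, and 3 when only the compared groups were fitted. Without U-bottom replicate 1 the calls were 107 higher and 119 lower.

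Experiment 5 repeated the U-bottom comparison and added 7 days. edgeR called 0 of 24174 identifiers at 1 day (1445 at an unadjusted p under 0.05, DESeq2 172), 2 at 3 days (2817, DESeq2 466) and 0 at 7 days (1841, DESeq2 141). At 3 days SMED30034030 had 1.37 ± 1.00 CPM in U-bottom libraries and 0 counts on flat plates, with a floor of 0.0429 CPM, and SMED30016911 had 0 counts in U-bottom libraries, with a floor of 0.046 CPM, and 9.25 ± 2.53 CPM on flat plates. SMED30024144, higher in U-bottom plates in experiment 3, had a log2 fold change of 1.53 at 3 days here (adjusted p = 0.407). RLE scaling gave 4 higher and 2 lower calls at 3 days. The 3-day count was 17 without flat replicate 2 and 0 without U-bottom replicate 1, the 1-day count 1 and 2 without U-bottom replicates 1 and 3, and the 7-day count 3 without flat replicate 1.

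Across all identifiers the U-bottom changes of experiments 3 and 5 had a Pearson's r of 0.0661 at 1 day (rho 0.0563) and 0.0393 at 3 days (rho 0.0846), over 19362 identifiers. Over the 4585 identifiers of at least 10 CPM r was 0.194 at 1 day and 0.267 at 3 days. Identifiers are not independent replicates and the experiments share no libraries. No identifier was called in both. The difference between the U-bottom changes at 7 days and at 1 day in experiment 5 gave 0 calls by edgeR, with 1701 at an unadjusted p under 0.05 and 124 by DESeq2.

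The 4 most abundant identifiers took a larger share of counts in U-bottom than in flat plates at each of the 5 day and experiment combinations. The difference averaged 5.51 percentage points, at an exact stratified permutation p of 2.94e-05 (adjusted 0.000588 over 20 tests). Within experiments the share was 73.6% ± 1.85 against 67.8% ± 2.26 at 1 day and 77.1% ± 5.91 against 68.3% ± 2.65 at 3 days in experiment 3. In experiment 5 it was 60.5% ± 1.74 against 57.0% ± 3.46, 69.6% ± 1.41 against 63.1% ± 3.61 and 66.5% ± 3.5 against 63.6% ± 0.67 at 1, 3 and 7 days (n = 3 each). The U-bottom response score differed by -0.01 on average, at an exact stratified permutation p of 0.943. A higher mean share of these 4 identifiers was not limited to U-bottom plates. The PA gel averaged 5.36 points above flat plates, higher at 2 of 3 days (exact stratified permutation p = 0.042, adjusted 0.103). The share at 3 days was 81.3% ± 4.70 on the gel (n = 2). HFF1 cells averaged 3.96 points above, higher at 1 of 2 days (exact stratified permutation p = 0.16, adjusted 0.246). The MEF difference was 6.37 points (exact stratified permutation p = 0.025, adjusted 0.0714).

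The PA gel of 100 Pa tested a soft substrate against the flat plate in experiment 3. edgeR called 0 of 20949 identifiers at 1 day (1259 at an unadjusted p under 0.05, DESeq2 21), 11 at 2 days (8 higher and 3 lower) and 25 at 3 days (10 and 15). At 2 days SMED30029780 was at 31.0 ± 10.8 CPM on the gel and 10.4 ± 1.63 CPM on flat plates (n = 3 each), a log2 fold change of 1.58 (SE 0.27, adjusted p = 0.0163). SMED30031308 was at 42.5 ± 5.47 and 100.1 ± 18.1 CPM, a change of -1.24 (SE 0.20, adjusted p = 0.0158). At 3 days SMED30013692 was at 400.0 ± 85.0 CPM (n = 2) on the gel and 144 ± 22.4 CPM (n = 3) on flat plates (adjusted p = 0.00437), and SMED30024144, higher in U-bottom plates, was lower on the gel, 4.42 ± 1.46 against 15.6 ± 4.88 CPM (adjusted p = 0.017). The 2-day count was 0 without flat replicate 1 or 3 or gel replicate 2 or 3, 2 without flat replicate 2 and 83 without gel replicate 1. The 3-day count was 0 without gel replicate 2, 3 without flat replicate 1 and 68 without flat replicate 3, and 1 with only the compared groups fitted. Its split turned to 25 higher and 7 lower without flat replicate 2, 15 and 7 without gel replicate 1, 142 and 127 by DESeq2, 154 and 110 without a low-count filter and 92 and 85 with only identifiers of at least 10 CPM. Without the 4 most abundant identifiers it was 8 and 6.

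The rose group had medians of -0.47, -0.29 and -0.59 on the gel over 282 identifiers at 1, 2 and 3 days, and of -0.46 in U-bottom plates at 1 day. Of its members 0, 0 and 1 were called lower and none higher (0, 1 and 3 lower and 0, 1 and 0 higher adjusted over the list alone), and adjusted p was 0.165, 0.256 and 0.186 with an estimated correlation. The response score was lower on the gel at each of the 3 days (mean difference -0.51, exact stratified permutation p = 0.0045, adjusted 0.0225), with -1.98 ± 0.34 against -1.52 ± 0.39 at 1 day, -1.27 ± 0.30 against -0.79 ± 0.06 at 2 days and -1.32 ± 0.34 (n = 2) against -0.73 ± 0.37 (n = 3) at 3 days. Without gel replicate 2 of day 1 the adjusted p was 0.056, and without gel replicate 2 of day 3 it was 0.0714.

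Feeder layers of HFF1 or MEF cells were tested in experiment 4 as support for neoblasts. With HFF1 feeders, edgeR called 0 of 26107 identifiers at 1 day (2597 at an unadjusted p under 0.05, DESeq2 832) and 1 at 3 days (1584, DESeq2 185). SMED30003527 was that identifier, at 205 ± 30.1 CPM with HFF1 cells and 1.25 ± 1.27 CPM on flat plates (n = 3 each), a log2 fold change of 7.35 (SE 0.99, adjusted p = 0.00142). It stood at 54.6 ± 11.8 CPM with HFF1 cells and 4.45 ± 3.06 CPM on flat plates at 1 day, at 0.566 ± 0.135 and 0.898 ± 0.508 CPM with MEF cells at 1 and 3 days, and at 0 counts in uncultured cells, with a floor of 0.0255 CPM. Its call at 3 days was lost without flat replicate 1 (adjusted p = 0.246) or 3 (adjusted p = 0.237), and with only the compared groups fitted (adjusted p = 0.121).

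With MEF feeders 0 identifiers were called at 1 day (3605 at an unadjusted p under 0.05, DESeq2 1166) and 0 at 3 days (2263, DESeq2 449). Without MEF replicate 3, 534 were called at 3 days. MEF replicates 1 and 2 at 3 days had 7480255 and 6775383 counts and put 3.98% and 3.33% of their non-dominant counts in identifiers silent in the uncultured cells of other experiments, while replicate 3 had 19777036 counts and 1.25%. The fell group had a median of -0.39 and the rose group of -0.35 with MEF cells at 3 days, 0 of 297 and 0 of 292 members passing the test (adjusted over the list alone, 0 of the fell group passed, and 1 of the rose group was higher and 5 lower), where the median of all identifiers was 0.63. Adjusted p was 0.0397 and 0.0321 with an estimated correlation, and with RLE scaling both medians turned positive, with 3 of the rose group higher (38 higher and 8 lower adjusted over the list alone). With RLE the adjusted camera p was 0.327 for the rose group. It was 0.00789 for the fell group, which still lay below the other identifiers. With HFF1 cells at 3 days the rose group had a median of -0.27 (0 of 292 passing, adjusted p = 0.0397 with an estimated correlation), which also turned positive with RLE scaling (0 passing adjusted over the list alone with TMM and 4 higher with RLE). Its adjusted camera p with RLE was 0.304.

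SMED30003527 was the only call of the direct contrast of the 2 feeders, at 1 day (log2 fold change 6.58 for HFF1 over MEF, SE 0.97, adjusted p = 0.00662) and at 3 days (7.80, SE 1.02, adjusted p = 0.000755). DESeq2 called 1011 and 139 identifiers in these contrasts. The median standard error at 10 CPM and above was 0.90 for HFF1 and 0.91 for MEF cells against flat plates at 3 days, and 0.206 for the U-bottom comparison at 3 days in experiment 3.

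Planarian tissue extract in U-bottom plates was tested in experiment 5 at 1, 3 and 7 days. At 1 day 459 of 24174 identifiers differed, 266 higher and 193 lower than in U-bottom plates without extract. RNA of the cells and RNA in the extract cannot be told apart here. SMED30022580, which flat culture lowered, stood at 63.3 ± 25.6 CPM with extract and 2.86 ± 0.53 CPM without at 1 day (n = 3 each), and at 34.3 ± 13.1 and 0.22 ± 0.252 CPM at 3 days, a log2 fold change of 7.26 at 3 days (SE 1.30, adjusted p = 0.000539) and -0.13 at 7 days (adjusted p = 0.983). SMED30026078 was lower at 1 day, 4.34 ± 0.86 against 34.8 ± 7.67 CPM (-3.0, SE 0.41, adjusted p = 4.97e-05). The 1-day calls were 348 higher and 487 lower without the day 7 libraries, 254 and 279 with only the compared groups fitted and 39 and 61 without extract replicate 2. Their number was 290, 186 and 218 without U-bottom replicates 1, 2 and 3.

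At 3 days 691 identifiers differed with extract, 248 higher and 443 lower. SMED30015024 fell from 20.7 ± 7.52 to 1.22 ± 1.13 CPM (n = 3 each), a log2 fold change of -4.06 (SE 0.79, adjusted p = 0.00183). SMED30008091, which rose in flat culture, was a further 3.43 higher on the log2 scale with extract (adjusted p = 3.28e-06). The count was 375, 365 and 453 without extract replicates 1, 2 and 3, and 408 and 394 without U-bottom replicates 1 and 3. DESeq2 called 957 higher and 863 lower, and without a low-count filter the calls were 507 and 410. A fit without the day 7 libraries called 1563 identifiers.

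At 7 days 1452 identifiers were called, 227 higher and 1225 lower, and with RLE scaling 493 higher and 520 lower. DESeq2 called 1269 higher and 1115 lower, and a fit of only identifiers of at least 10 CPM 770 and 569. SMED30003372 was lower under both, 1.75 ± 1.75 against 49.3 ± 6.67 CPM without extract (n = 3 each), a log2 fold change of -4.80 (SE 0.59, adjusted p = 3.51e-06), and SMED30034693 was at 2.16 ± 2.94 against 30.9 ± 14.0 CPM (-3.85, SE 0.65, adjusted p = 0.000166). SMED30035218 was higher, 21.8 ± 20.7 against 0.382 ± 0.237 CPM (5.93, SE 0.91, adjusted p = 5.59e-05). The count was 697 without U-bottom replicate 2, 790 without U-bottom replicate 3 and 81 with only the compared groups fitted, where these 3 identifiers had adjusted p of 0.0565, 0.126 and 0.052.

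With extract the rose group passed at no day with an estimated correlation between identifiers, and the fell group only at 1 day. At 1 day the rose group had a median of 0.93, with 46 of 277 identifiers higher and 5 lower (78 and 14 adjusted over the list alone), and at 7 days of 1.15, with 40 higher and 27 lower (85 and 39). Adjusted p was 0.165 and 0.256 with an estimated correlation. Extract replicate 2 at 1 day had a response score of 2.25, against 0.94 and 1.30 in replicates 1 and 3, and without it 39 identifiers of all those tested were called higher at 1 day, fewer than these 46. The fell group had a median of -0.13 at 1 day, with 5 of 389 identifiers higher and 6 lower (7 and 8 adjusted over the list alone) and an adjusted p of 0.0288 with an estimated correlation. At 3 days the medians were 0.46 and 0.13, with 7 higher and 20 lower in the rose group (11 and 24 adjusted over the list alone), 16 higher and 7 lower in the fell group (21 and 9), and adjusted p of 0.997 and 0.526 with an estimated correlation. The fell group at 7 days had a median of 0.22, with 18 higher and 18 lower (21 and 24 adjusted over the list alone) and an adjusted p of 0.913. With RLE scaling the 7-day median was 1.59 in the rose group, with 76 higher and 11 lower (117 and 19 adjusted over the list alone), and 0.68 in the fell group, with 27 higher and 4 lower (34 and 5), at adjusted p of 0.184 and 0.999 with an estimated correlation.

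The 4 most abundant identifiers held 41.0% ± 2.70 of counts with extract at 1 day against 60.5% ± 1.74 without, 52.8% ± 5.15 against 69.6% ± 1.41 at 3 days and 67.9% ± 2.47 against 66.5% ± 3.5 at 7 days (n = 3 each). Over the 3 days the difference averaged -11.6 percentage points (exact stratified permutation p = 0.0035, adjusted 0.0225). SMED30032887, the most abundant, had log2 fold changes of -1.37 and -1.65 at 1 and 3 days (adjusted p = 2.61e-05 and 1.43e-07) and 0.78 at 7 days (adjusted p = 0.00335). The 7-day change depends on the scaling, whose mean TMM factor was 0.457 with extract and 0.709 without at 7 days. The unscaled share of the largest identifier in each 7-day library overlapped between these groups. It was 53.3%, 46.6% and 56.1% with extract and 36.0%, 53.9% and 52.6% without. Identifiers silent in the uncultured cells of other experiments took a larger share of the remaining counts with extract at each of the 3 days, 0.315% ± 0.182 against 0.149% ± 0.0242, 0.445% ± 0.0602 against 0.295% ± 0.0208 and 2.34% ± 0.18 against 1.34% ± 0.33. The exact stratified permutation p was 0.00025, the smallest possible (adjusted 0.0025).

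**Figure D4:**
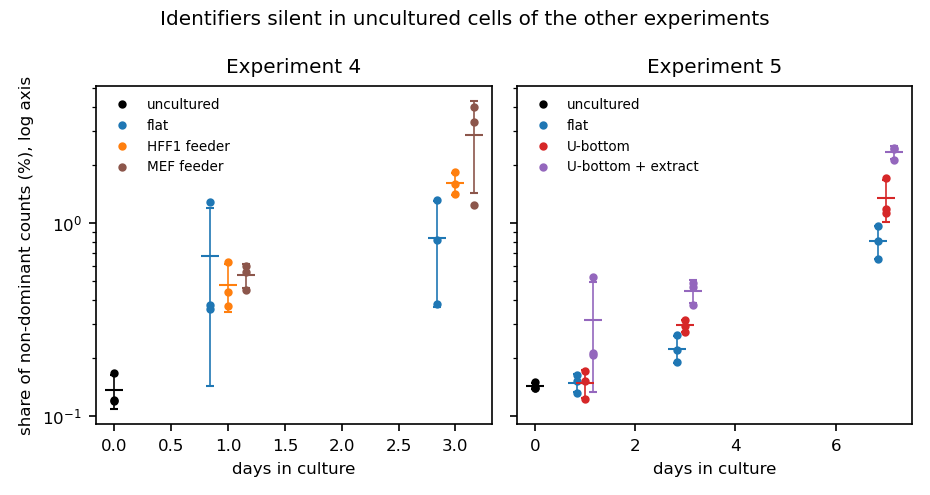
Percent of counts outside the 4 most abundant identifiers that fell on identifiers silent in uncultured cells of the other experiments (y axis, log scale), in each library (points) against days in culture (x axis), with group means and SD as bars; points of a day are set side by side. In experiment 5 the flat libraries averaged 0.149% at 1 day and 0.812% at 7 days, and the extract libraries 2.34% at 7 days.

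The extract changes at 7 days and at 1 day differed for 366 identifiers, 44 more positive and 322 more negative at 7 days. RLE scaling gave 61 and 88 such identifiers, and a fit of only identifiers of at least 10 CPM 143 and 113. SMED30022580 had log2 fold changes of 4.47 at 1 day (adjusted p = 0.0247) and -0.13 at 7 days, and its 1-day call was lost without U-bottom replicate 1, 2 or 3 (adjusted p = 0.0922, 0.147 and 0.0975) or extract replicate 2 (adjusted p = 0.122).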

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

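Chosen only after the results were seen were the tests of scaling, of the most abundant identifiers at 7 days with extract, of feeder RNA, the correlation with the 1-day change and the share of abundant identifiers for the exchange of labels, and all counts of other splits of the libraries. The change with extract differed between 7 days and 1 day for 366 identifiers by a test of the difference itself, and 4 of 60 splits gave as many, the highest other split giving 674. The 60 splits, a draw from all possible ones, mixed the labels of each day separately. A split can keep the extract labels of 1 day and mix the other, so its count can hold the extract change itself. These counts therefore cannot judge chance for the difference, and chance is not excluded. The difference between the HFF1 and MEF changes was called for 1 identifier at 1 day and 1 at 3 days, SMED30003527 in both, and only 1 of 10 splits, the real one, gave a call in each case, the highest other being 0. The difference between the U-bottom changes at 7 days and 1 day gave 0 calls by edgeR (1701 at an unadjusted p under 0.05, 124 by DESeq2). All 60 of 60 splits matched this, the highest other giving 1, but any split matches a count of 0, so this says nothing about chance.

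Comparisons of 3 libraries with 3 have 10 splits, so a share is never under 0.1 and chance cannot be judged from them. For AggreWell plates 1 split, the real one, gave 3828 calls or more, the highest other giving 1. For extract 1 split did so at each day, with 459 real against 2 at 1 day, 691 against 1 at 3 days and 1452 against 150 at 7 days. For flat culture against uncultured cells 1 split did so in each comparison and the highest other was 0, with real counts of 5876, 7890 and 8765 in experiment 3, 4352 and 4134 in experiment 4, and 166, 892 and 2466 in experiment 5. For U-bottom plates 2 splits in experiment 3 gave the 2 calls of 1 day, the highest other giving 2, and 3 splits gave 227 calls or more at 3 days, the highest other giving 595. In experiment 5, 4 splits gave the 2 calls of 3 days, the highest other giving 7. For the PA gel at 2 days 1 split gave 11 calls, the highest other giving 0, and for HFF1 cells at 3 days 1 split gave 1 call, the highest other giving 0. All 10 splits matched the edgeR counts of 0 for aggregates, the PA gel at 1 day, HFF1 cells at 1 day, MEF cells at 1 and 3 days, and U-bottom plates at 1 and 7 days in experiment 5, with highest others of 0, 1, 2, 0, 2, 2 and 0. At an unadjusted p under 0.05 these had 305, 1259, 2597, 3605, 2263, 1445 and 1841 identifiers, and DESeq2 called 2, 21, 832, 1166, 449, 172 and 141.

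Of the 1452 calls with extract at 7 days, 84.4% were lower. With the 4 most abundant identifiers removed 85.6% were lower. TMM already trims such identifiers from the scaling, so their removal is a weak test of whether they made the imbalance. With RLE scaling 51.3% of 1013 calls were lower, and DESeq2 (46.8% lower) and a fit of only identifiers of at least 10 CPM (42.5% lower) made higher calls the majority, so the scaling between libraries may account for the excess of lower calls. The direction of single identifiers such as SMED30003372, lower under both scalings, is not touched by this. Whether extract lowered more identifiers than it raised stays open.

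Identifiers silent in the uncultured cells of other experiments took more of the counts in flat culture than in uncultured cells, at 1 day already in experiment 3 (2.96% against 1.68%) and experiment 4 (0.672% against 0.136%) and without overlap from 3 days in experiment 5 (0.224% against 0.143%), which may reflect transcription that begins in culture or RNA from elsewhere. The 1-day mean of experiment 4 leaned on flat replicate 2, with 0.358%, 1.28% and 0.375% in replicates 1, 2 and 3. RNA of feeder cells cannot be the whole cause, since the flat libraries of experiment 5 at 7 days, which had no feeder, lay 0.669 percentage points above uncultured cells. Over 5780 such identifiers the rank correlation between flat and extract libraries at 7 days in experiment 5 was 0.268, against 0.291 and 0.282 within the groups, a quotient of 0.934, which is what 1 shared profile in these libraries would give, though all 3 correlations are weak and other experiments were not tested. This profile may equally come from the cells themselves, and no biological explanation was tested. RNA in serum, in the medium or, where it was added, in the extract stays open too.

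The flat and U-bottom libraries of experiment 3 at 3 days split more strongly across the groups than between them. Flat replicates 1 and 2 with U-bottom replicate 3, against the other 3 libraries, gave 595 calls (318 higher and 277 lower), against 227 for the labelled groups, which points to a structure of the samples. Without the 4 most abundant identifiers this split still gave 571. Their removal is a weak test of them as its cause, since TMM already trims such identifiers. An exchange of labels between flat replicate 3 and U-bottom replicate 3 moved the correlation with the 3-day U-bottom change of experiment 5 by only -0.0537, from 0.267 to 0.214 over 4585 identifiers, which leaves it open, while 2 other values go against it: the correlation with the 1-day U-bottom change of experiment 3 went from 0.133 to -0.346, and U-bottom replicate 3 held 83.1% of counts in the 4 most abundant identifiers against 67.8% in flat replicate 3, the direction of the group means at 1 day and in experiment 5. A difference in handling or cell state between these libraries stays open and may be the source.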

How the results depend on the processing

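Removal of the 4 most abundant identifiers, the fit of identifiers of at least 10 CPM, the fit without day 7, the halved library and all library measures were chosen after seeing the data. The gene lists matched no identifier, so no alternative for them was run, and the cause of the changes given here was not tested unless stated. Of the recomputed counts and correlations that answer a comparison, 229 stayed near the reported value and 142 did not. For counts this meant within 1.5 times. For correlations it meant a difference on Fisher's z scale inside the 95% interval for that number of identifiers. DESeq2 called 2 identifiers for aggregates, 150 and 633 for U-bottom plates at 1 and 3 days and 21, 117 and 269 for the PA gel at 1, 2 and 3 days in experiment 3. It called 832 and 185 with HFF1 cells, 1166 and 449 with MEF cells and 6924 and 6474 for flat culture at 1 and 3 days in experiment 4, and 1011 and 139 between the feeders. In experiment 5 it called 172, 466 and 141 for U-bottom plates, 1235, 1820 and 2384 for extract and 636, 2162 and 4139 for flat culture at 1, 3 and 7 days, and 124 and 823 for the differences of the U-bottom and extract changes between 7 days and 1 day. RLE scaling gave 7 calls with MEF cells at 3 days, 6 for U-bottom plates at 3 days in experiment 5 and 149 for the difference of the extract changes. It moved the median log2 fold change of all identifiers in experiment 3 flat culture from -0.03 to -0.14, -0.01 to -0.14 and -0.09 to -0.21 at 1, 2 and 3 days. In experiment 4 it moved it from -0.36 to -0.52 and 0.39 to 0.64 with HFF1 cells, -0.58 to -0.73 and 0.63 to 1.17 with MEF cells and 0.30 to 0.61 and 0.21 to 0.56 in flat culture, and in experiment 5 from 0.19 to 0.31 for U-bottom plates at 7 days, 0.24 to 0.68 for extract at 7 days and -0.11 to -0.25 for flat culture at 1 day. Among the 50 medians of the culture-response groups it reversed 3 whose camera adjusted p with TMM and an estimated correlation was under 0.05. The rose group with HFF1 cells at 3 days went from -0.27 to 0.0303 (adjusted p = 0.304 with RLE). With MEF cells at 3 days the rose group went from -0.35 to 0.14 (adjusted p = 0.327) and the fell group from -0.39 to 0.0295. That fell group still lay below the other identifiers, which is the direction of its adjusted p of 0.00789. Medians with a higher p changed sign too: the fell group with HFF1 cells went from 0.11 to -0.032 at 1 day and -0.074 to 0.22 at 3 days. Without a low-count filter, 6 identifiers were called for aggregates, 115 and 520 for U-bottom plates and 102, 198 and 264 for the gel in experiment 3, 95, 182 and 86 for U-bottom plates in experiment 5, 714 for extract and 462 for flat culture at 1 day there, and 31 for the difference of the U-bottom changes. Removal of the 4 most abundant identifiers left 14 calls for the gel at 3 days. For flat culture in experiment 4 it raised the calls from 4352 to 6148 at 1 day and from 4134 to 6120 at 3 days. Both stayed within 1.5 times. With only identifiers of at least 10 CPM, and so fewer tested, 1769 were called for AggreWell plates, 14 for U-bottom plates at 1 day, 2, 74 and 177 for the gel and 2703, 3071 and 3103 for flat culture in experiment 3, 5 and 7 with HFF1 and MEF cells at 3 days, 810 and 727 for flat culture in experiment 4, and 758 and 1055 for extract at 1 and 3 days and 342 for flat culture at 1 day in experiment 5. With these identifiers Pearson's r of the U-bottom changes was 0.194 at 1 day and 0.267 at 3 days, that of flat culture 0.825 and 0.755 between experiments 3 and 5 and 0.479 and 0.731 between 4 and 5, and 0.513 at 3 days between 3 and 4. With only the 2 compared groups fitted, 9 and 3 were called for U-bottom plates, 18, 69 and 1 for the gel and 9659 for flat culture at 1 day in experiment 3, 0 with HFF1 cells at 3 days by edgeR (1584 at an unadjusted p under 0.05 with all groups, 185 by DESeq2), 1674 for flat culture at 1 day in experiment 4, and in experiment 5, 0 for U-bottom plates at 3 days, 1129 and 81 for extract at 3 and 7 days and 1860, 2335 and 4854 for flat culture. Without day 7, 20 were called for U-bottom plates at 3 days, 835 and 1563 for extract and 476 and 1565 for flat culture at 1 and 3 days. Leaving out each library in turn gave 0 to 1 calls for aggregates and 970 to 3884 for AggreWell plates. In experiment 3 it gave 0 to 27 and 100 to 478 for U-bottom plates, 0 to 0, 0 to 83 and 0 to 68 for the gel and 3901 to 4713, 5974 to 6463 and 7016 to 8079 for flat culture. In experiment 4 it gave 0 to 0 and 0 to 1 with HFF1 cells, 0 to 0 and 0 to 534 with MEF cells and 662 to 3876 and 667 to 3831 for flat culture. In experiment 5 it gave 0 to 2, 0 to 17 and 0 to 3 for U-bottom plates, 100 to 389, 365 to 517 and 697 to 1690 for extract and 61 to 210, 465 to 745 and 1451 to 1914 for flat culture. With the replicate number as a replicate block, 5 were called for aggregates, 1813 for AggreWell plates and 151 for U-bottom plates at 3 days in experiment 3, and 26 other counts stayed within 1.5 times. Libraries of the same number deviated together, at r above 0.1, in 2 of 3 pairs of experiment 1, 1 of 3 of experiment 2, 23 of 100 of experiment 3, 3 of 63 of experiment 4 and 16 of 135 of experiment 5, so the number was not taken as a pairing. In experiment 1 the mean r was 0.384 for the same number and -0.173 for other pairs, so a pairing there stays open. The 5 calls under its block were 3 higher and 2 lower. In experiment 3 some flat and gel libraries of 3 days were deposited under column numbers other than the replicate numbers used here. Their same-number pairs may therefore be misaligned. Of the recomputed values of identifiers named by the rule, 738 kept their call and 83 lost it, 67 of these with 1 library left out, and none changed sign. Of those of library measures 351 kept their side of the threshold, 15 lost and 5 gained a call. For MEF cells at 3 days, whose shallowest library had 6775383 counts, 22.7% of simulated log2 changes of 3, planted at about 10 CPM or more, were recovered. The shallowest library of all, with 3333661 counts, was U-bottom replicate 1 at 1 day in experiment 5, and the effect of depth alone was not tested.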

Other observations

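The measures and identifiers described here were all chosen after seeing the data. The number of detected identifiers moved in opposite directions between experiments in flat culture. It went from 22466 ± 379 in uncultured cells to 16036 ± 267 at 3 days and 19977 ± 1376 at 7 days in experiment 5, and from 22167 ± 307 to 29338 ± 2811 at 3 days in experiment 4 (n = 3 each, each without overlap with uncultured cells, exact permutation p = 0.1, the smallest possible). With extract it was higher than without by 1699 on average over 3 days, in 2 of them (exact stratified permutation p = 0.011, adjusted 0.044), and the adjusted p rose above 0.05 without any 1 of 13 libraries, to at most 0.0714. MEF cells had a share of counts in the 4 most abundant identifiers 6.37 percentage points above flat plates (exact stratified permutation p = 0.025, adjusted 0.0714), with an adjusted p of 0.0367 without MEF replicate 2 of day 3.

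SMED30003527, the identifier called with HFF1 cells in experiment 4, stood in experiment 3, which had no feeder, at 12.4 and 17.6 CPM in flat replicates 1 and 2 and at 18.1 CPM in U-bottom replicate 3 at 3 days, and at no more than 3.20 CPM in every other library of that experiment. Those 3 libraries detected 20823, 19508 and 18878 identifiers, the other flat and U-bottom libraries of that day 22718, 22096 and 21996, and the 2 gel libraries 23280 and 21481.

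In replicate 2 of the extract group at 3 days, 0.0102% of the detected identifiers had an odd count, while this share lay between 35.7% and 46.8% in the other libraries of experiment 5. With its counts halved, the 691 calls of extract at 3 days moved by less than 1.5 times. MEF replicates 1 and 2 at 3 days were the shallowest of experiment 4, and U-bottom replicate 1 at 1 day, with 3333661 counts, that of experiment 5.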
